A study of Mus musculus with 8 samples.

How the data were processed

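The data are processed values of 8 Affymetrix arrays of primary mouse aortic smooth muscle cells, 4 from control cultures and 4 from cultures given 100 nM jasplakinolide for 24 h. The deposited values are log2 expression levels of 35556 probe sets, made with RMA in Affymetrix Expression Console, per the submitters' processing notes, and their range of 2.29 to 14.2 is that of log2 values. Versions of these programs are not given in the sources used here. Detection calls were not used here, so no probe set is called absent. The labels do not say whether the replicates come from separate cultures or animals. The p-values therefore measure the spread between these samples, which may be technical. The number of arrays, 4 per group, limits the precision.

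Probe sets were named from the platform annotation: 21789 had 1 gene symbol, 1621 several and 12146 none, and those with several or none were left out of the tests. Gene identifiers of 21698 probe sets matched the reference gene table, which changed 0 symbols. Where a gene had more than 1 probe set (999 genes), the one with the highest mean over the 8 arrays was kept, which left 19938 genes. No gene named by the rule given below had more than 1, and genes named outside that rule were not checked for this. No genome build was needed and no coordinates are given. No filter on dim probe sets was used.

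Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, two-sided) with Benjamini-Hochberg adjustment over all genes, and a gene was said to have changed at an adjusted p under 0.05. The residual degrees of freedom were 6 and the prior degrees of freedom 3.43. Errors of log2 differences are limma's standard errors, and those of group means are SDs. A fold change is 2 to the power of the log2 difference. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

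The design, the test, 24 gene lists, the rule for named genes and the main alternatives were chosen before the data were examined. By that rule, the text names the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap (predicted genes left out). It also names up to 4 members per list with the largest differences among those past the test (2, with values only, where none passed), and always Acta2, Tagln, Cnn1, Myh11, Myocd, Srf, Vcl, Ccn2, Ankrd1, Cacna1c and Cav1. Genes named outside it are said to have been chosen after their values were seen. List members without a value are not analysed here.

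Each list was tested with camera (limma), with a preset correlation between genes of 0.01 and with a correlation estimated from the residuals, and with fry, adjusted over the 24 lists. The p of fry tests whether a set's genes move, on balance, one way, and its mixed p whether they change in either direction; neither compares the set with other genes. The exact test of list medians over the 35 splits was added after the data had been seen. So were 2 more lists, of further endothelial genes and of further smooth muscle and mural cell identity genes, which were written before the values of their members were looked at.

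Replicate numbers are shared by the groups. Deviations of same-numbered arrays from their group means correlated at 0.24 to 0.56 across genes in all 4 pairs, and those of arrays with other numbers at -0.62 to 0.52; 6 of the 8 arrays correlated best with their own number. The exceptions were control 2 and jasplakinolide 4, which correlated best with each other (0.52). As every same-numbered pair was above 0.1, the numbers were taken to pair the samples. The pairing comes from the data and not from the labels. The fit without a block was kept as the main result, as chosen beforehand, with the blocked value beside results whose call or count it moved. Scan dates were not used here, and no batch other than the replicate number was tested.

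The fit was tested on simulated data with the genes, means and spread of this comparison (19938 genes, 200 of them changed, 10 runs). It recovered 21.6% of genes changed by 0.25 on the log2 scale, 91.6% at 0.5 and 100% at 1. On average 3.97% of its calls were false, and no gene or list was called where nothing had been changed. The simulated genes were drawn independently and without replicate structure. The simulation therefore cannot show how list calls with the preset correlation do where members move together. In the real data the estimated correlation was 0.56 for mitosis and 0.57 for DNA replication. Alternatives tried were the replicate block, filters to the brighter 75% or 50% of genes, median centring, a second quantile normalization, cyclic loess, an intensity trend with a robust prior, array weights, the mean of a gene's probe sets, every probe set on its own, adjusted p under 0.01, and leaving out each array in turn. Chosen after seeing the data were leaving out control 2 and jasplakinolide 4 together, the median olfactory receptor signal as a covariate (olfactory receptors taken as a measure of background), and the estimated correlation with the block.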

Results

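Gene expression was measured on 8 Affymetrix arrays in primary aortic smooth muscle cells of C57Bl6 mice at passage 3 to 4. All cultures were kept for 24 h in DMEM with 10% fetal calf serum, 4 without addition (control) and 4 with 100 nM jasplakinolide. Jasplakinolide is a cell-permeable compound from marine sponges that binds and stabilises actin filaments and promotes actin polymerisation. The values are log2 RMA expression levels, and 19938 genes were compared. Array medians over all probe sets lay between 7.30 and 7.39, and the arrays correlated with each other at 0.991 to 0.997 across probe sets, which are not independent replicates. On the first principal component (43.3% of the variance), control 2 (12.1) and jasplakinolide 4 (19.4) lay at one end, control 1 (-13.4) and control 3 (-14.3) at the other, and the remaining 4 arrays between -4.64 and 4.71. Control 2 and jasplakinolide 4 had the highest median signal over 1027 olfactory receptor genes (5.04 and 5.05 log2, against 4.91 to 4.97 on the other arrays). Transcripts of the Y-linked genes Eif2s3y (9.88 to 10.2 log2), Kdm5d (8.63 to 9.06) and Uty (9.42 to 9.88) were bright on all 8 arrays, while Xist lay at 5.02 to 5.40. The number of arrays limits the precision of every value given here.

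The comparison addresses how cultures labelled as vascular smooth muscle cells respond to jasplakinolide at the level of transcripts. By mean level over the 8 arrays, 7 of 12 endothelial markers were in the brightest 10% of genes, as were 7 of 19 contractile markers. Bulk arrays do not show which cells a change came from. Of 19 markers of contractile smooth muscle 10 rose (8 to 9 with any 1 array left out), and of 27 genes of mitosis 14 fell. The mitosis count was 17 without control 2, 3 or 2 without jasplakinolide 3 or 4, 1 without control 1, control 3, jasplakinolide 1 or jasplakinolide 2, and 0 without control 4. The median log2 difference of the mitosis genes stayed between -0.31 and -0.28 in these fits, each of which had 1 array fewer. The largest rise was that of Kcnmb1, the beta subunit of the large-conductance calcium-activated potassium channel of smooth muscle, from 8.27 ± 0.12 in control to 10.27 ± 0.29 log2 with jasplakinolide (SD, n = 4 each), a 4.00-fold difference. Cnn1, which encodes the actin-binding protein calponin, rose 2.53-fold from 11.14 ± 0.05 to 12.48 ± 0.16 log2 (SD, n = 4 each). The largest fall was that of Clec4e, a C-type lectin receptor best known from myeloid cells, from 10.07 ± 0.23 to 8.76 ± 0.24 log2 (SD, n = 4 each), 2.48-fold lower. Among mitotic genes, Cdc20, an activator of the anaphase-promoting complex, went from 10.32 ± 0.07 to 9.93 ± 0.05 log2 (SD, n = 4 each), 1.31-fold lower, and missed the threshold without control 4 (adjusted p = 0.0581).

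In all, 154 genes changed (limma, adjusted p under 0.05), 87 higher and 67 lower, and 10 of them changed at least 2-fold, 9 higher and 1 lower. The replicate number was also used as a block, since the numbers were taken, from the data, to pair the samples. With it 377 genes passed, 162 higher and 215 lower, 149 of them shared with the 154, and again 10 changed at least 2-fold. Most changes were small, with a median of 1.41-fold among the genes that rose and 1.29-fold among those that fell. In all 154 genes the 4 treated arrays lay on one side of the 4 control arrays. Among all genes tested, 1377 (6.91%) had groups that did not overlap, against 2.86% by chance. Leaving out single arrays gave fewer changed genes. The count was 43 without control 4, 52 without jasplakinolide 2, 55 each without control 3 and jasplakinolide 1, 59 without jasplakinolide 3, 71 without jasplakinolide 4, 78 without control 1 and 150 without control 2. The higher share of the calls was 87 of 154, and turned to 129 higher and 167 lower after another quantile normalization and to 129 and 168 after cyclic loess.

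The 9 genes that rose at least 2-fold included Kcnmb1 and Cnn1 (log2 difference 1.34 ± 0.07, SE). Ptprz1 (1.57 ± 0.15), a receptor-type tyrosine phosphatase, Efhd1 (1.47 ± 0.12), a calcium-binding protein, and Nppb (1.45 ± 0.14), the B-type natriuretic peptide, were among them. The others were the Popeye-domain genes Popdc2 (1.33 ± 0.10) and Bves (1.13 ± 0.07), Acta1 (1.26 ± 0.13), skeletal muscle alpha-actin, and Dmd (1.15 ± 0.11), which encodes dystrophin. Their adjusted p values ran from 0.000254 for Cnn1 to 0.00289 for Acta1. Synpo2 (0.98 ± 0.15, SE), an actin-binding protein of muscle, Ppbp (0.93 ± 0.09), a platelet chemokine, and Actg2 (0.93 ± 0.10), the gamma-actin of smooth muscle, completed the 12 largest rises. Each of the 9 and Clec4e passed the threshold whichever single array was left out.

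After Clec4e (-1.31 ± 0.14, SE), the largest falls were those of Clec4d (-0.86 ± 0.12), a receptor of the same family, Prom1 (-0.72 ± 0.06), which encodes prominin, Lcn2 (-0.65 ± 0.10), an iron-siderophore-binding lipocalin of inflammation, and Cftr (-0.62 ± 0.11), an epithelial chloride channel. The guanylate-binding protein gene Gbp4 (-0.59 ± 0.07), Gimap4 (-0.57 ± 0.09), Clca3a2 (-0.59 ± 0.10) and Clca3a1 (-0.57 ± 0.10) of the family of chloride channel regulators, Ceacam1 (-0.53 ± 0.09), a cell adhesion molecule, Ldb2 (-0.51 ± 0.08) and the lectin gene Clec1a (-0.50 ± 0.06) followed. Clca3a2 was the only one of them to miss the threshold with the replicate block (adjusted p = 0.0509). Cftr missed it after median centring (adjusted p = 0.0519), another quantile normalization (0.0900) and cyclic loess (0.0856), and Clca3a1 after median centring (0.0506). Prom1, Gbp4 and Clec1a kept their calls whichever array was left out, whereas Clec4d kept its call in 4 of the 8 fits, Lcn2, Gimap4 and Ldb2 in 2 each, and Cftr, Clca3a1, Clca3a2 and Ceacam1 in 1 each.

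**Figure D1:**
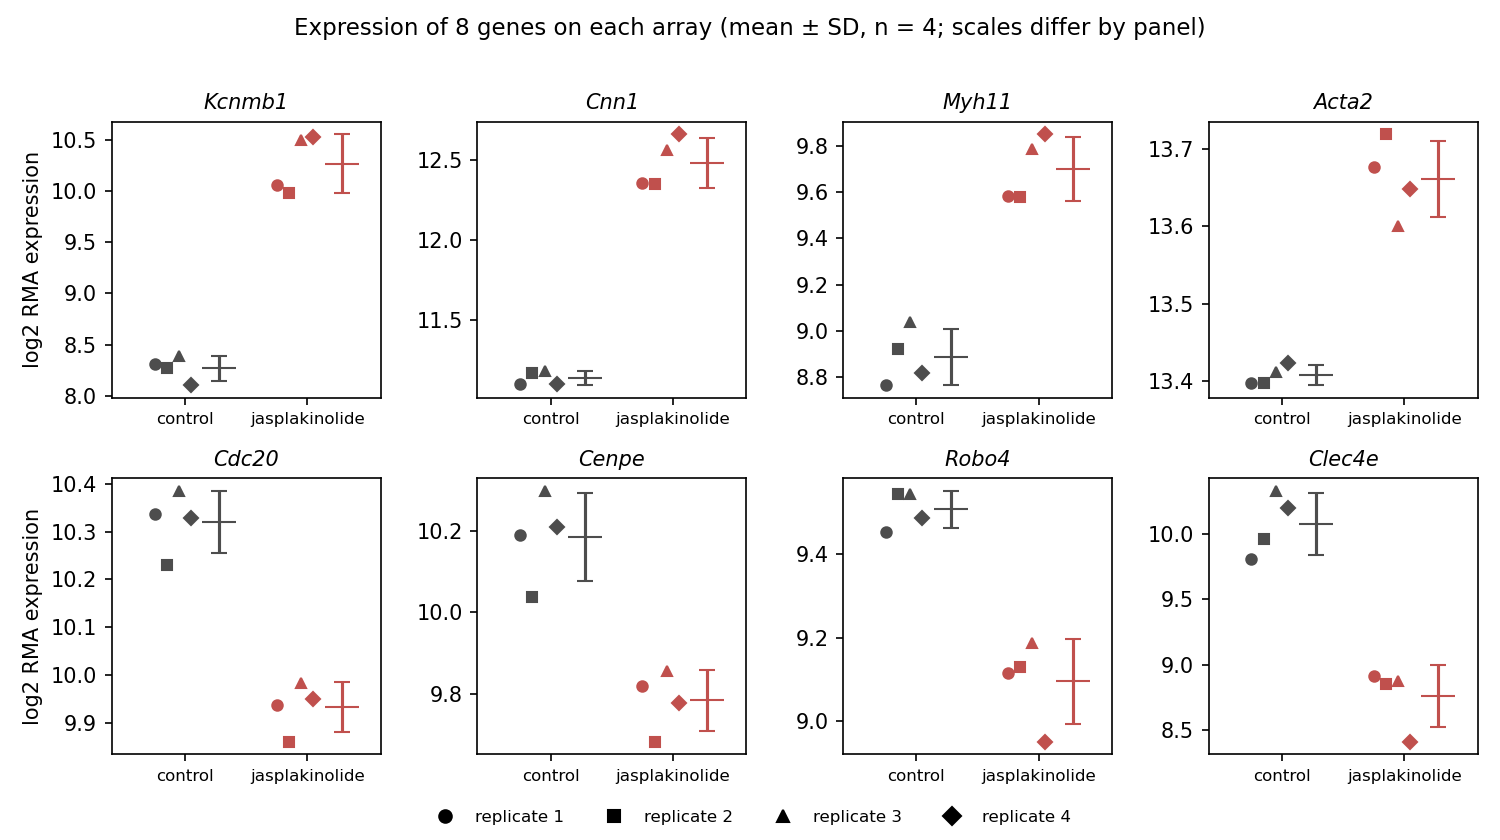
Log2 RMA expression of 8 genes on each of the 8 arrays, with marker shape for the replicate number and, beside the points, the mean ± SD of each group (n = 4). Kcnmb1, Cnn1, Myh11 and Acta2 lay higher on all 4 jasplakinolide arrays than on any control array, and Cdc20, Cenpe, Robo4 and Clec4e lower.

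Of 19 contractile and differentiation markers of smooth muscle, 10 rose, none fell and 9 did not pass the test, 14 rose when adjusted over the list alone, and 11 rose with the replicate block. Besides Kcnmb1, Cnn1, Synpo2 and Actg2, the smooth muscle myosin heavy chain Myh11 rose by 0.81 ± 0.08 (SE) and Tagln (transgelin) by 0.55 ± 0.04 on the log2 scale. Acta2 (smooth muscle alpha-actin) rose by 0.25 ± 0.04 (0.23 to 0.27 with 1 array left out), and it lost its call whenever any 1 of the 8 arrays was left out (adjusted p 0.0593 to 0.128). Tagln and Myh11 kept theirs in all 8 such fits, and Synpo2 lost its call without control 1 (adjusted p = 0.0643), control 4 (0.0899) or jasplakinolide 3 (0.0812). The list's median log2 difference was 0.55, and camera placed it above other genes (adjusted p = 1.386e-23; adjusted p = 0.0655 with an estimated correlation). Myocd, the coactivator myocardin, differed by 0.13 ± 0.09 (SE) and did not pass. In the same comparison 1 of 12 endothelial markers passed the test, lower, with a list median log2 difference of -0.11 (adjusted p = 0.0941 with an estimated correlation). None of 25 further endothelial genes passed, with a median of -0.06, and 2 of them fell with the replicate block.

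Of 29 cytoskeletal and adhesion genes known as targets of serum response factor and its actin-regulated cofactors, 3 rose, none fell and 26 did not pass. Adjusted over the list alone, 17 rose, and 5 rose with the replicate block. The 3 were Acta1, Fhl1 (0.31 ± 0.05, SE), a LIM-domain protein, and Flnc (0.26 ± 0.04), an actin crosslinker of muscle. The median was 0.14, with 26 members above 0 (camera adjusted p = 7.691e-17; adjusted p = 0.0655 with an estimated correlation). Srf itself differed by 0.05 ± 0.05 and the focal adhesion gene Vcl (vinculin) by 0.17 ± 0.05 (SE), and neither passed. The count of these genes that rose was 6 after median centring, 5 after another quantile normalization or cyclic loess, 8 with array weights and 14 with an intensity trend and robust prior. It was 2 without control 1 or control 2 and 1 without any other single array. Acta1 remained in all 8 fits, Fhl1 kept its call in 2 of the 8 fits and Flnc in none. Of 26 regulators of actin turnover, 2 rose, Scin (scinderin, an actin-severing protein) by 0.47 ± 0.07 and Dstn (destrin, which depolymerises actin) by 0.35 ± 0.05 (SE), and 24 did not pass. Each kept its call in 2 of the 8 fits with an array left out. Adjusted over the list alone, 3 rose and 1 fell, and with the replicate block 2 rose and 1 fell. That list's median was 0.05 (camera adjusted p = 0.00461; adjusted p = 0.323 with an estimated correlation), and without control 2 it was not called (adjusted p = 0.0564). None of 10 caveolar genes passed, and 1 rose when adjusted over the list alone. Their median was 0.06 (camera adjusted p = 0.0165; adjusted p = 0.131 with an estimated correlation; adjusted p = 0.110 without control 2 and 0.100 without control 2 and jasplakinolide 4). Cavin3 had the largest difference, 0.42 ± 0.10 (SE), and passed with the replicate block (adjusted p = 0.0380). Cav3 differed by 0.10 ± 0.06 and Cav1 by 0.08 ± 0.04.

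All 27 measured genes of mitosis and cytokinesis had a lower mean with jasplakinolide. Of these, 14 fell and 13 did not pass, 26 fell when adjusted over the list alone, and 21 fell with the replicate block. After another quantile normalization or cyclic loess 22 fell, with array weights or with an intensity trend and robust prior 23, and after median centring 13. The largest falls were those of Cenpe (-0.40 ± 0.06, SE), a kinetochore motor, Cdc20 (-0.39 ± 0.05), the microtubule depolymerase Kif2c (-0.39 ± 0.07) and the spindle protein Nusap1 (-0.38 ± 0.06). The list's median was -0.30 (camera adjusted p = 1.419e-42; adjusted p = 0.0655 with an estimated correlation). Leaving out 1 array kept the median between -0.31 and -0.28. The count that passed was 0 without control 4, 1 without control 1, control 3, jasplakinolide 1 or jasplakinolide 2, 2 without jasplakinolide 4, 3 without jasplakinolide 3 and 17 without control 2. Cdc20 lost its call only without control 4 (adjusted p = 0.0581), and Cenpe, Kif2c and Nusap1 kept theirs only without control 2. All 25 measured genes of DNA replication also had a lower mean, with a median of -0.15 (camera adjusted p = 3.203e-19; adjusted p = 0.147 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, fell by 0.27 ± 0.05 (SE) but missed the threshold whichever array was left out (adjusted p 0.0640 to 0.155). It also missed it after median centring and with the olfactory receptor signal as a covariate. The other 24 did not pass, and 18 fell when adjusted over the list alone. After another quantile normalization or cyclic loess 5 of the 25 fell, and after median centring 0 did.

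Of 12 endothelial markers, 1 fell and 11 did not pass, 6 fell when adjusted over the list alone, and 3 fell with the replicate block. Robo4, a guidance receptor of endothelial cells, fell by 0.41 ± 0.06 (SE), but missed the threshold (adjusted p 0.0580 to 0.0729) without control 3, control 4, jasplakinolide 1 or jasplakinolide 2. The list's median was -0.11 (camera adjusted p = 2.954e-06; adjusted p = 0.0941 with an estimated correlation). Interferon-stimulated genes and p53 targets were called lower with none of 19 and none of 17 members past the test, over all genes or adjusted over the list alone. Of the interferon-stimulated genes, 1 fell with the replicate block. Their medians were -0.09 (camera adjusted p = 0.00627; adjusted p = 0.627 with an estimated correlation) and -0.02 (camera adjusted p = 0.0231; adjusted p = 0.627 with an estimated correlation). Neither list was called without control 1 (adjusted p = 0.460 and 0.220) or jasplakinolide 4 (0.196 and 0.346), and the p53 targets were not called without control 3 (adjusted p = 0.0776). Both also lost their calls with the olfactory receptor signal as a covariate (adjusted p = 0.239 and 0.305), with array weights (0.469 and 0.462) and without control 2 and jasplakinolide 4 together (0.107 and 0.189). The p53 targets were not called among the brighter 75% or 50% of genes (adjusted p = 0.0538 and 0.0600). The largest differences were those of Rtp4 (-0.40 ± 0.16, SE), Gbp3 (-0.34 ± 0.13; adjusted p = 0.0275 with the replicate block), Mdm2 (-0.20 ± 0.08) and Sesn2 (-0.17 ± 0.09).

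**Figure D2:**
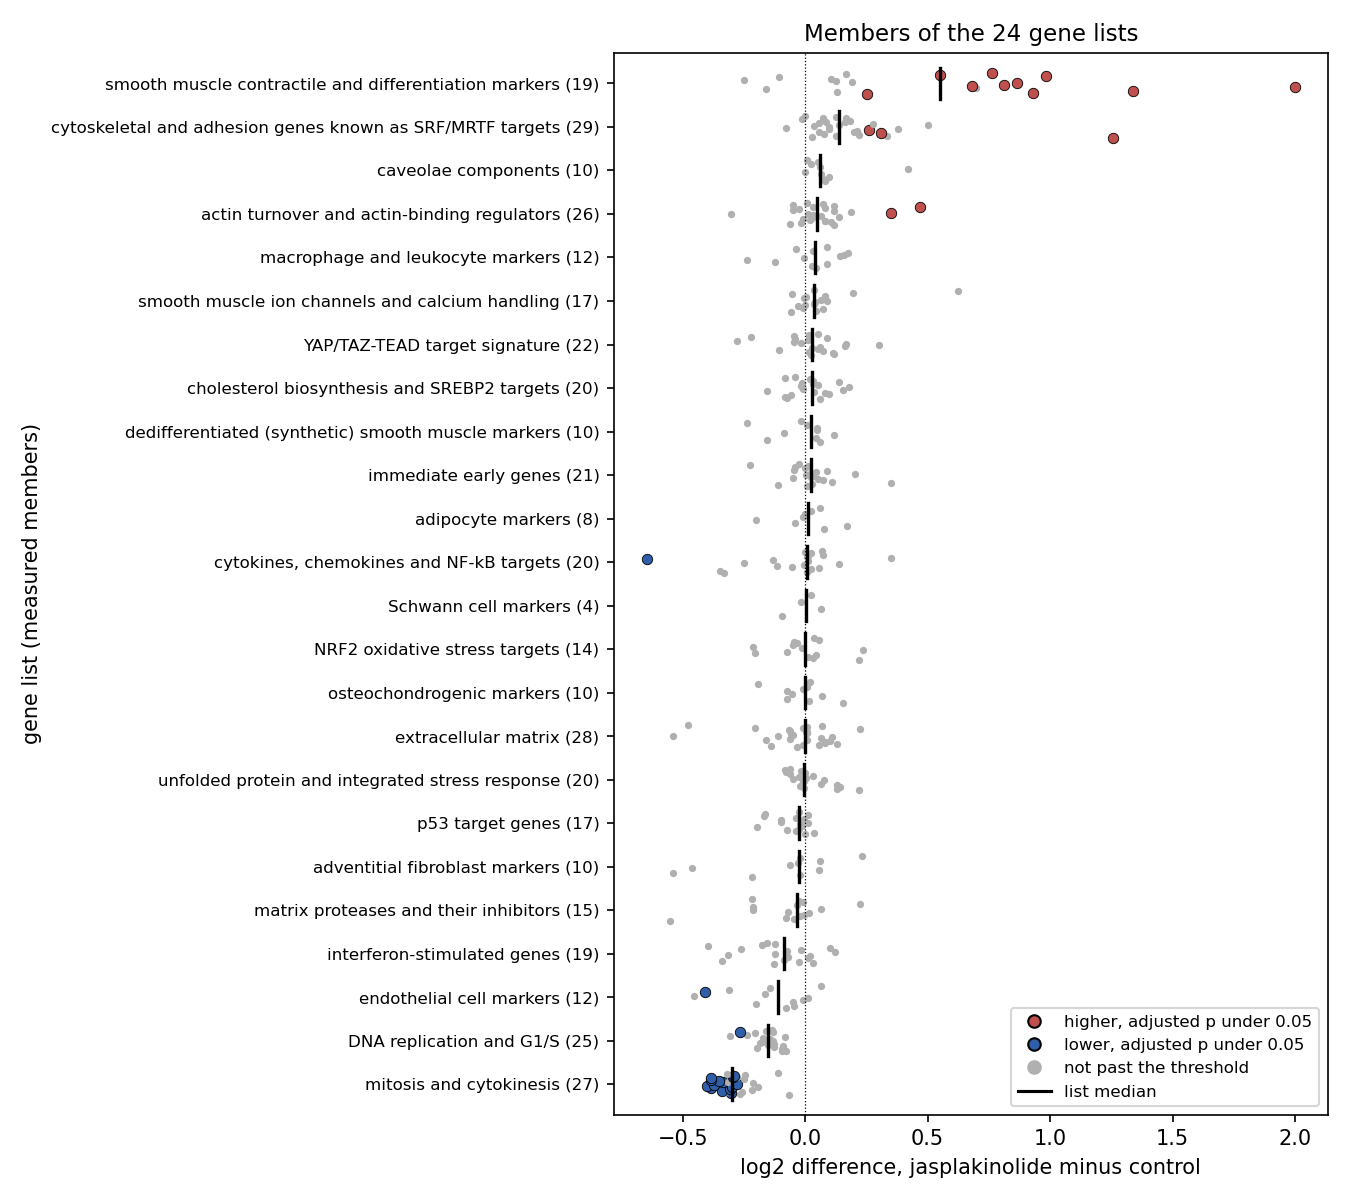
Log2 difference, jasplakinolide minus control, of each measured member of the 24 gene lists, with 1 point per gene, colour for genes past adjusted p of 0.05 and a bar at each list's median. The contractile markers have the highest median (0.55) and the genes of mitosis the lowest (-0.30).

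The other 15 lists were not called (camera adjusted p 0.0643 to 0.968), and their medians lay between -0.03 for matrix proteases and 0.04 for macrophage markers. Lcn2, among 20 cytokines, chemokines and NF-kB targets, was the only member of these 15 lists to pass, and 4 members of its list fell when adjusted over the list alone and 2 with the replicate block. Among 22 targets of YAP and TAZ, none passed by either adjustment. Ccn2 differed by 0.03 ± 0.04, Ankrd1 by 0.12 ± 0.04, F3 by 0.30 ± 0.09 and Igfbp3 by -0.28 ± 0.10 (SE). Among 21 immediate early genes none passed by either adjustment, with Egr1 at 0.35 ± 0.12 and Nr4a2 at -0.23 ± 0.13. Of 28 extracellular matrix genes none passed and 1 fell when adjusted over the list alone. Dcn (decorin) differed by -0.54 ± 0.12 and Vcan (versican) by -0.48 ± 0.22, and both passed with the replicate block (adjusted p = 0.0134 and 0.0251). Among 15 matrix proteases and inhibitors none passed by either adjustment, with Adamts1 at -0.55 ± 0.15 and Plaur at 0.22 ± 0.09. With the block both passed (adjusted p = 0.0240 and 0.0468), and the list was called lower (camera adjusted p = 0.0242), as it was without jasplakinolide 1 (0.0404) and after another quantile normalization (0.0466), but not with an estimated correlation (0.192, and 0.266 with the block). Among 17 ion channel and calcium handling genes none passed by either adjustment. Trpc6 differed by 0.62 ± 0.17, passing with the block (adjusted p = 0.0141), Trpc1 by 0.19 ± 0.09 and Cacna1c by 0.07 ± 0.11. That list was called higher among the brighter 50% of genes (adjusted p = 0.0479), but not with an estimated correlation over all genes (0.425).

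Markers of dedifferentiated smooth muscle (10 measured; Tnfrsf11b -0.24 ± 0.13 and Klf4 -0.16 ± 0.06, SE), osteochondrogenic markers (10; Sox9 -0.19 ± 0.12 and Acan 0.16 ± 0.09) and cholesterol synthesis genes (20; Msmo1 0.18 ± 0.06 and Insig1 0.16 ± 0.08) had no member past the test by either adjustment. Genes of the unfolded protein and integrated stress response (20; Asns 0.22 ± 0.05 and Chac1 0.14 ± 0.06) and NRF2 targets (14; Hmox1 0.23 ± 0.09 and Abcc1 0.22 ± 0.05) had none past it, and each had 1 member higher when adjusted over the list alone. Markers of other cell types had none past it either. They were 12 of macrophages (Cd68 -0.24 ± 0.07, adjusted p = 0.0424 with the block, and Lyz2 0.17 ± 0.05), 10 of adventitial fibroblasts (Dcn, and Dpt at -0.46 ± 0.11), 8 of adipocytes (Fabp4 -0.20 ± 0.08 and Cd36 0.17 ± 0.13) and 4 of Schwann cells (Cdh19 -0.09 ± 0.07 and Ngfr 0.06 ± 0.10). Adjusted over the list alone, 1 macrophage marker rose and 1 fell, 1 fibroblast marker rose and 2 fell, and no adipocyte or Schwann cell marker passed. With the replicate block, 1 macrophage marker fell, and 1 fibroblast marker rose and 1 fell. The inflammatory list without jasplakinolide 1 (adjusted p = 0.0388) and the fibroblast list without control 3 (adjusted p = 0.0441) were called lower, with the preset correlation; over all 8 arrays neither was called with an estimated correlation (0.627 and 0.425).

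Median, mean and camera direction differed in sign for 6 of the lists that were not called. The median was above 0, with a direction of down, for cytokines and chemokines (median 0.0062, mean -0.056), dedifferentiation markers (0.024 and -0.018), adipocyte markers (0.010 and 0.0099) and Schwann cell markers (0.0029 and -0.0063). It was below 0, with a direction of up, for the stress response (-0.0050 and 0.019) and for NRF2 targets (-0.00058 and -7.0e-05). For extracellular matrix genes fry gave a direction of up, with a median of -0.0026, a mean of -0.037 and a camera direction of down.

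Of the 24 lists, 9 were called by camera with its preset correlation, 4 higher and 5 lower, and none kept its call with an estimated correlation, with or without the replicate block. With that correlation, camera gave 6 lists an unadjusted p under 0.05, and 2 with the block. By fry, 7 lists passed in 1 direction (contractile, serum response factor targets, actin turnover, caveolae, mitosis, DNA replication and endothelial) and 13 in either direction. The 13 were these 7 and the YAP and TAZ, stress response, NRF2, cytokine and chemokine, macrophage and fibroblast lists. The mixed adjusted p of fry was 2.456e-07 for the stress response and 0.00430 for YAP and TAZ targets, against 2.176e-05 for the contractile list. An exact test over the 35 splits of the 8 arrays gave 0.0286, the smallest p it can give, for the medians of the contractile, serum response factor, caveolae, mitosis and DNA replication lists (two-sided). For the endothelial and actin turnover lists the exact p was 0.0571, as 2 of the 35 splits, the real one among them, gave a median as large. After Benjamini-Hochberg adjustment over the 24 lists the exact p of 0.0286 became 0.137, and no list passed. A p that cannot be smaller passes this adjustment only if many lists reach it. The test takes all 35 splits as exchangeable, which pairing by replicate number puts in doubt. Among the 8 splits that part all 4 pairs, the smallest share possible is 0.125.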

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

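The check of single arrays was fixed before the result was seen, and no test in this part was chosen afterwards. Among the named genes, 154 sets of 4 arrays (1 gene in 1 group) were looked at for 1 array far from the other 3, and in 7 the gap to the nearest array took a larger share of the whole range than Dixon's critical value for 4 arrays. About 1 in 20 sets exceeds it by chance, or 7.7 here. Jasplakinolide 4 was the low array for Clec4e (gap 0.882 of the range; 8.41 log2 against 8.86 to 8.92 on the other treated arrays), Lcn2 (0.899) and Clca3a2 (0.836), all of which fell. Control 1 was the high array for Bves (0.894; 8.22 log2 against 7.94 to 7.97 on the other controls) and Rtp4 (0.849). Jasplakinolide 3 was the low array for Scin (0.904) and control 3 for Cdh19 (0.889). No explanation was tested for these.

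In a test over every probe set, 2 of the 50 that passed carried several gene symbols or none, and both were lower with jasplakinolide (log2 difference -0.58 with 4 symbols and -0.33 with none). They are named by no gene here.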

How the results depend on the processing

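Leaving out control 2 and jasplakinolide 4 together, the olfactory receptor covariate and the estimated correlation with the block were chosen only after the results were seen. The number of genes changed at least 2-fold stayed between 9 and 11 under every alternative it was run under. All 154 changed genes kept their direction wherever they were tested, which is no added support. Leaving arrays out could not turn a direction, since the groups of these genes did not overlap. The block, the brightness filters and the intensity trend leave the log2 differences unchanged. Of the 37 named genes that passed, 36 passed with the replicate block and 18 (without control 4) to 33 (without control 2) with 1 array left out. The number of genes higher, 87, was 162 with the replicate block, 155 among the brighter 50% of genes, 193 with an intensity trend and robust prior, 223 with array weights, 40 over every probe set, 37 at adjusted p under 0.01 and 52 without control 2 and jasplakinolide 4. The number lower, 67, was 215 with the replicate block, 110 and 141 among the brighter 75% and 50% of genes, 167 after another quantile normalization, 168 after cyclic loess, 165 with the trend, 234 with array weights, 10 over every probe set and 8 at adjusted p under 0.01. Without 1 array, 35 (control 4) to 67 (control 2) were higher, with 46 without control 3 and 45, 43, 41 and 53 without jasplakinolide 1 to 4. Likewise 8 (control 4) to 83 (control 2) were lower, with 20 without control 1, 9 without control 3 and 10, 9, 18 and 18 without jasplakinolide 1 to 4. Filters test fewer genes and a stricter threshold passes fewer; for the other settings the cause was not tested. Of 24 lists 9 were called, but 0 with an estimated correlation, 0 when this was joined with the block, 7 by fry and 13 by fry in either direction. Contractile, serum response factor, mitosis, DNA replication and endothelial lists were called in all 19 settings that kept the preset correlation. The block turned 8 named genes past the threshold and Clca3a2 below it, and changed the call of no other named gene; of the lists, it added the matrix proteases. Signs turned for Ngfr (-0.0082 with the olfactory covariate) and Cacna1c (-0.058 with array weights, -0.065 without control 2 and jasplakinolide 4, and -0.018 to 0.14 with 1 array left out, the lowest without jasplakinolide 4), neither of which passed. The cause was not tested. Without detection calls, the signal over background of dim genes stays unknown.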

Other observations

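The tests of the contractile and endothelial lists with a background covariate were chosen only after the results were seen. So were that of the spread of endothelial genes and that of their brightness against lists of brighter genes. The genes named in the next paragraph and the single endothelial genes named further below were also chosen after their values were seen. The other tests here were set out before their results were seen.

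Single genes outside the lists also passed; those given here were picked by hand, so they test no group. Lims2, a focal adhesion adaptor, rose by 0.79 ± 0.07 (SE), Mustn1 by 0.72 ± 0.05, Tgfb3, a transforming growth factor, by 0.70 ± 0.10, and Sync (syncoilin, of intermediate filaments) by 0.64 ± 0.06 on the log2 scale. The small heat shock protein Hspb6 rose by 0.63 ± 0.09, Ppp1r14a, an inhibitor of myosin phosphatase, by 0.56 ± 0.06, and Enah, which promotes actin filament elongation, by 0.56 ± 0.09. Hmmr (-0.45 ± 0.08), Ckap2 (-0.41 ± 0.07), Cep55 (-0.37 ± 0.05), Ncapg (-0.36 ± 0.06), a condensin subunit, the kinase Nek2 (-0.33 ± 0.06) and the cytokine Il11 (-0.40 ± 0.07) fell. All of these passed with the replicate block as well.

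The contractile list was higher with jasplakinolide, with a median log2 difference of 0.55, 10 of 19 genes past the test and 3 below 0. Camera with an estimated correlation did not call it (adjusted p = 0.0655, and 0.266 with the block). A larger share of smooth muscle cells in the treated cultures would raise other genes of that identity about as much. The median of 12 such genes above median brightness was 0.12 (bootstrap 95% interval 0.028 to 0.15), below the bound of 0.27 that was set. That bound took the contractile median as exact, although its own interval was wide (0.13 to 0.78 with the covariate below). Against the fixed bound the values argue against this share as the whole cause, but a bound with its own spread was not tested. Any of the 12 genes that other cells in the cultures also express would rise less. With the olfactory receptor signal as a covariate, 10 contractile genes passed, as many as without it. The signal overlapped between the groups (4.91 to 5.04 log2 in control, 4.95 to 5.05 with jasplakinolide), so the covariate had little group difference to remove. The kept count therefore does not decide on background as a cause. The test first set out, on the list's median (0.54, interval 0.13 to 0.78, bound 0.27), did not decide and was replaced. A response to the compound may account for the rise, as a hypothesis found and tested on the same data.

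Endothelial genes were bright on all 8 arrays, in cells labelled as smooth muscle: 7 of 12 markers were in the brightest 10% of genes. The 4 brightest markers were Emcn at 13.39, Cdh5 at 13.13, Esam at 12.49 and Pecam1 at 12.40 log2. The dimmest were Vwf at 8.11 and Cldn5 at 7.76 log2, and Cldn5 lay below the median of all genes, 7.91. In comparison, 7 of 19 contractile, 3 of 10 fibroblast, 0 of 12 macrophage, 0 of 8 adipocyte and 0 of 4 Schwann cell markers were that bright, where probe affinities differ and brightness is not a share of cells. Of 25 further endothelial genes 9 were in the brightest 10%, against 6 at the 99th percentile of 10000 random lists of all genes, which argues against a few bright or cross-hybridising probe sets in the first list as the whole cause; lists drawn only from genes above median brightness, a pool chosen by brightness itself, had 10 at that percentile, which 9 does not exceed. No gene of either endothelial list is in the contractile list. Endothelial cells in the cultures and expression of these genes by the smooth muscle cells both stay open as candidate explanations, untested, since bulk arrays hold no value that separates them.

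The first endothelial list was lower with jasplakinolide, with a median of -0.11, whereas the median was -0.06 for 25 further endothelial genes, none of which passed (2 with the replicate block, lower), and -0.04 for the 16 bright genes of both lists. With the olfactory receptor covariate, which ended the calls of the interferon and p53 lists, the first list was still called (camera adjusted p = 6.890e-05 with the preset correlation). Without the covariate, camera with an estimated correlation gave an adjusted p of 0.0941, and 0.295 with the block. With the covariate, the list's median lay beyond the midpoint between 0 and the median without it, by -0.066 (bootstrap interval over genes taken as independent, -0.11 to -0.0037). The signal overlapped between the groups (4.91 to 5.04 log2 in control, 4.95 to 5.05 with jasplakinolide), so the covariate had little group difference to remove. The test therefore does not decide on background as a cause. Background that the olfactory receptor signal does not track was not tested. This was the third test of the background question. It was written after a first one, on the interval of the median alone (-0.24 to -0.022, bound -0.056), had not decided. A second one, on the call alone, had come out on the same side as the third. A smaller share of endothelial cells would lower these genes alike, and the SD of the differences of the 16 bright ones, from Egfl7 (-0.20) to Adgrl4 (0.11), was 0.089, with a bootstrap interval (0.061 to 0.11, added after the SD had been seen) that spanned the 0.079 reached at most by 1 common fall in 95% of simulations, but lay above the 0.056 reached with the SEs of the replicate block. An SD as large as 0.089 came in a share of 0.009 of these simulations, and of 0 with the SEs of the replicate block. By the SD alone, 1 common fall of these genes was therefore rare with either set of SEs. The interval of the SD still reached below the bound without the block. A smaller endothelial share and a response to the compound were thus not told apart for these genes.

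All 35 ways to split the 8 arrays into 4 and 4 were run. For genes changed at least 2-fold, 1 of the 35 splits, the real one, gave as many (10, against 2 at most in the others), and chance can be excluded only if all 35 are taken as exchangeable, which replicate numbers that pair the samples put in doubt; the 8 splits that part all 4 pairs (10, against 0 at most in the other 7) are too few for a share under 0.05. For genes higher it cannot be excluded, since 3 splits gave as many (87 in the real split, 633 at most in another), nor for genes lower, with 2 splits (67, and 113 in another), or for lists called with the preset correlation, with 6 splits (9, and 11 at most in another). In splits other than the real one the direction is arbitrary, as control 1 was always put in the first group. Exchanging the groups turns the 633 higher genes into lower ones, and chance cannot be excluded either way. The splits that called other genes followed replicate numbers: replicates 1 and 3 against 2 and 4 gave 746 genes, several times the 154 of the real split, and replicates 1 and 2 against 3 and 4 gave 149. Replicates 1 and 4 against 2 and 3 gave 0. The splits that called genes point to a structure of the samples by replicate number. With that number as a block, 377 genes differed between control and jasplakinolide. Among the 8 splits that part all 4 pairs, as the real one does, the other 7 gave 0 genes each with limma, and none gave as many lists.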
